A study of Mus musculus with 8 samples.

How the data were processed

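RNA from subcutaneous white adipose tissue of wild-type mice fed ad libitum (AL) or calorie restricted (CR) was sequenced as paired-end libraries. The labels name both ribosomal RNA depletion and poly-A purification and state 400000000 reads per sample. The submitters' processing notes name FastQC 0.12.1, STAR 2.7.10b, SAMtools 1.17, featureCounts 2.0.3 and edgeR 3.38.4 and the genome build GRCm39, without giving the role of each. The gene annotation, the strand setting of the counting and the test behind the FDR column are not given in the sources used here, so values of antisense and overlapping genes are uncertain. The deposited table gives TPM values by the authors, 1 value per Ensembl gene and library, and an adjusted p-value (FDR) by the authors. The smallest deposited FDR among the rows analysed here was 0.0500, with 242 rows from 0.05 to 0.06 and 41928 at 1. Rows with a smaller value were not analysed here, and the TPM columns were used without rescaling in the main comparison.

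The design was fixed before the data were examined and assumed 8 libraries. The table holds 7, of which 3 are AL and 4 are CR, so filters and tests were applied to these. Columns were assigned to diets by their names, and 0 columns were left without a group. Column numbers do not follow the mouse numbers of the labels, so no library was matched to 1 mouse. Of 50952 rows 6680 had no gene symbol and 16 had a whole number in its place, and 1831 of these were named through their Ensembl identifier in GENCODE M21. That annotation, of build GRCm38, served for names, gene types, lengths and overlaps, and no coordinate is compared with the deposited build. It covers 46037 of the rows.

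Genes with at least 1 TPM in at least 4 libraries were tested (9883 genes). Values were log2(TPM + 1), fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) with diet as the only term and moderated variances with a trend. Two-sided p-values were adjusted by Benjamini-Hochberg over all tested genes, and a gene was called at an adjusted p under 0.05. Calls of at least 2-fold also needed an absolute log2 change of 1. Because the median change differed from 0, the same fit was also run after each library was divided by its median ratio to the geometric mean over tested genes, and relative changes, their standard errors and 95% confidence intervals come from that fit. Gene lists were tested with camera at a preset correlation of 0.01, for lists with at least 3 tested genes, with fry and with an estimated correlation beside it. Members were also adjusted over the list alone. The difference in TPM held was tested by an exact permutation test over 35 assignments, which is two-sided.

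Within a library, TPM multiplied by gene length is a whole multiple of 1 step, the value of 1 read, and reads per gene were recovered by dividing by that step, with M21 lengths. Of 22040 rows judged, those above 0 with up to 1000 reads per library, 20839 (94.55%) were within 0.05 of a whole number in every library. Recovered reads served as a measure of depth and for 2 of the alternatives. Depth ranged from 4147864 to 8897824 reads in rows with a length. After rescaling the median standard error of a log2 change was 0.134. The procedure was tested on simulated data with 4 against 3 libraries and 9387 tested genes, in which it recovered 22.4% of 1.5-fold, 83.6% of 2-fold and 100% of 4-fold changes, with 3 false calls, and 19.4% of 1.5-fold changes with 4 false calls after median-ratio scaling. Changes were placed only in genes with many reads, at a fixed dispersion of 0.02 and with no common shift. These rates therefore do not cover rows with few reads.

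Named genes followed a rule fixed before the data were examined. It took the coactivators of the Ncoa family with Lep, Adipoq, Pparg, Ppargc1a, Fasn and Ucp1. It also took up to 10 genes per direction with the largest called change, a mean of at least 5 TPM in one group and no overlap between groups (leaving out provisional symbols that begin with Gm or end in Rik and rows with no symbol). From each described list it took up to 4 members with the smallest adjusted p or, where none passed, up to 2 with the highest mean. The 5 genes with the highest mean TPM completed it. The pool for the second part held 7 genes that were higher and 1549 that were lower. Genes that passed after rescaling, or adjusted over a list alone after rescaling, were added after their values were seen. Pseudogene transcripts were matched to protein-coding transcripts with blastn (megablast) of BLAST 2.17.0 at 90% identity or more over at least 100 bases. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for tables, permutation and Fisher's exact tests and plots.

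Alternatives fixed beforehand were pseudocounts of 0.1, 0.5 and 5, no filter, a mean of at least 5 TPM, median-ratio scaling, quantile normalization, totals without mitochondrial and the 20 most abundant genes. They also included no variance trend, robust moderation, array weights, a surrogate variable, an exact permutation test per gene, an estimated list correlation, fry, and leaving out each library. Added after seeing the data were a filter of 1 TPM in 3 libraries, a mean of at least 10 recovered reads, voom on recovered reads, and leaving out each library with median-ratio scaling. A replicate block, a count-based test named for a table of counts, and the Ncoa2 comparison were not run.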

Results

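The series measured RNA in subcutaneous white adipose tissue of wild-type C57BL/6J mice fed ad libitum (AL) or kept on calorie restriction (CR) for 6 months, from 3 to 9 months of age. The labels list 8 mice, 4 per diet, and the table analysed here holds 7 libraries, 3 AL (named AL2, AL3 and AL4) and 4 CR (CR1 to CR4). It gave TPM (read abundance scaled by gene length and library total) for 50952 genes, of which 25497 were at 0 in every library. The rows analysed here had no deposited false discovery rate (FDR) under 0.05 in the authors' deposited table, so genes under that value are outside the comparison below, which describes the remaining transcriptome, and adjusted p-values here are over a set without them. Of 22028 protein-coding genes in the GENCODE M21 annotation, 5658 had no row among those analysed here, while 1106 of 1107 olfactory receptor genes had one. The 13 genes encoded by mitochondrial DNA were listed at 0 in all 7 libraries.

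TPM of a whole library sum to a fixed total, of which the rows held 51.2% ± 2.06 in AL (SD, n = 3) and 43.6% ± 0.946 in CR (SD, n = 4). This difference of 7.57 percentage points was larger than the spread between mice and had the smallest p that the 35 assignments allow (two-sided exact permutation p = 0.0286). The permutation took the rows as given, after those with a deposited FDR under 0.05 had been left out. Leaving out such rows can by itself shift the share that remains, so this p cannot tell a diet difference from that choice. The reads behind each value were recovered from the TPM steps. The rows with a known gene length held 6881177 ± 1884809 reads per AL library (SD, n = 3) and 5100042 ± 680815 per CR library (SD, n = 4). The 7 libraries ranged from 4147864 to 8897824 reads. These are totals of the rows analysed here, not of whole libraries. Over whole libraries the steps gave 2988473 to 5531659 reads per kilobase of gene, so rows not analysed here do not account for the gap to the 400000000 reads per sample that the labels state, and its cause was not tested. Counting error is only part of the spread between mice. Correlations of log2(TPM + 1) over the tested genes lay between 0.9607 and 0.9708 within AL, between 0.9686 and 0.9747 within CR, and between 0.9517 and 0.9687 across diets. Principal components were taken from the same genes after median-ratio scaling. The first held 29.05% of the variance and separated the diets, with AL at -31.9, -17.2 and -11.0 and CR between 13.8 and 15.9. The library farthest out was AL3, in which Bhlhe40, a repressor in the circadian clock, stood at 14.0 TPM against 113 to 158 TPM in the other libraries. The interferon-stimulated gene Rsad2 was highest in AL3, at 50.6 TPM.

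**Figure D1:**
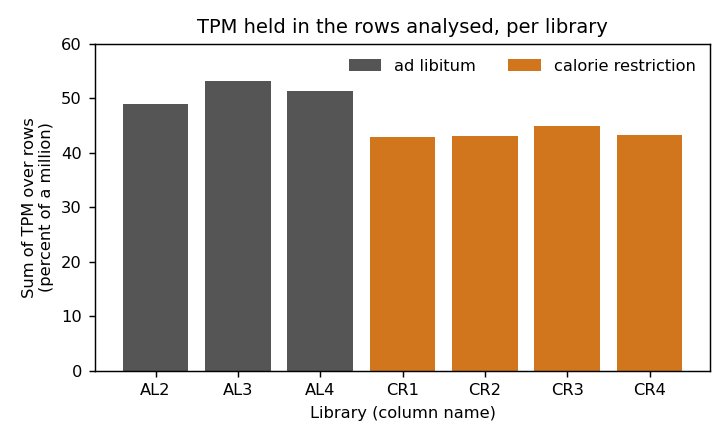
The percent of a library's TPM total held by the analysed rows is plotted as 1 bar per library on an axis from 0, with AL in grey and CR in orange. The 3 AL bars reach up to 53.1% and all stand above the 4 CR bars, which lie between 42.9% and 45.0%.

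The comparison of CR with AL asked which genes calorie restriction altered in this fat depot, with lipid metabolism and transcriptional regulators such as the nuclear receptor coactivator Ncoa2 named as the focus. Relative to the typical gene, genes of branched-chain amino acid breakdown and of insulin signalling moved in both directions, with 7 of 9 and 6 of 11 tested members past the test after median-ratio scaling when adjusted over the list alone. Over all genes, 0 of them passed after that scaling, and on the deposited scale 2 and 6 fell and 0 rose. At an unadjusted p under 0.05 after that scaling stood 7 of 9 and 6 of 11 of these members and 29.0% of all tested genes. So did 14 of 25 autophagy and lysosome genes and 6 of 12 antioxidant genes. Neither of the 2 lists was called by camera after that scaling (adjusted p = 0.623 and 0.789). Ncor1, a corepressor of nuclear receptors, fell from 87.2 ± 11.4 TPM in AL (SD, n = 3) to 56.0 ± 4.57 TPM in CR (SD, n = 4) on the deposited scale. On that scale 33 of 54 tested ribosomal protein genes, 15 of 65 splicing factors and 5 of 13 endothelial markers also fell, as did 17.6% of all tested genes. After median-ratio scaling 0 of these members were called over all genes, and adjusted over the list alone 2 ribosomal protein genes rose and 4 fell, 6 splicing factors rose and 2 fell, and 0 endothelial markers passed. The coactivators Ncoa5, Ncoa6 and Ncoa7 did not pass the test. Across the tested genes the typical change was small and downward on the deposited scale, with a median of -0.20 in log2(TPM + 1). Changes relative to that shift are therefore given beside the calls, after each library was divided by its median ratio to the other libraries, and called relative changes, while TPM are as deposited. Relative changes are log2 differences CR minus AL with their standard error (3 AL and 4 CR libraries), and the added 1 TPM understates the change of genes with low TPM. Relative to the typical gene, 89.7% of the 9883 tested genes lay within 0.5 log2 units of 0.

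On the deposited scale limma called 1796 genes at an adjusted p under 0.05, of which 54 rose and 1742 fell. After median-ratio scaling 5 genes rose and 0 fell in the same test, while 1557 genes were higher and 1308 lower at an unadjusted p under 0.05, together 29.0% of those tested. At an adjusted p under 0.1 after that scaling, 823 genes were higher and 512 lower, 648 and 450 of them protein coding. Of the 1742 genes that fell on the deposited scale, 1594 were protein coding, 1735 were also lower relative to the typical gene, and 1143 of them had an unadjusted p under 0.05 there. These genes were chosen for their falls in the same libraries, so the 1735 and 1143 largely follow from that choice and are no separate result. A test with voom on the recovered reads called 0 genes and gave 2998 at an unadjusted p under 0.05. At least 2-fold changes were called on the deposited scale for 60 genes, 32 higher and 28 lower, and for 5 after median-ratio scaling and 8 at a pseudocount of 5. With a filter of 1 TPM in 3 libraries, 35 were higher and 45 lower on the deposited scale. Without AL3, CR1, CR2, CR3 or CR4 the 60 became 31, 31, 18, 30 and 33. On the deposited scale groups did not overlap for 3285 genes (33.2%), 214 higher and 3071 lower, a count that includes the shift of all genes. After median-ratio scaling they did not overlap for 2623 genes (26.5%), 1372 higher and 1251 lower, where chance gives 5.71%. Leaving out AL3, CR1, CR2, CR3 or CR4 took the 1796 calls to 725, 765, 662, 1032 and 1170.

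**Figure D2:**
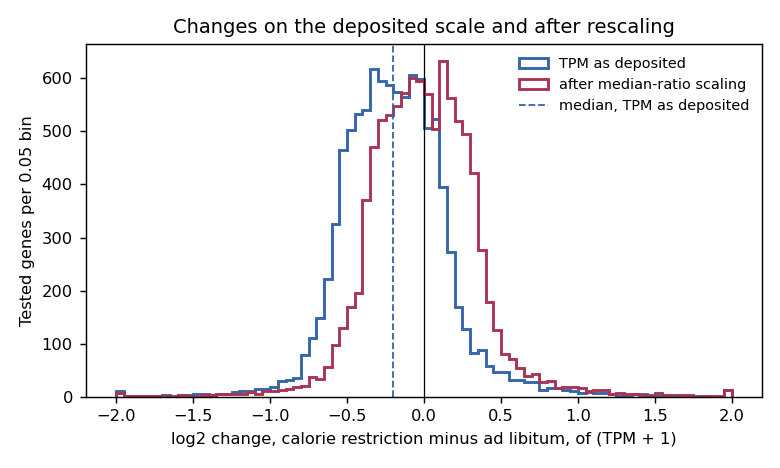
Histograms give the number of tested genes by log2 change, CR minus AL, on the deposited scale and after median-ratio scaling, with the outermost bins holding all values beyond -2 and 2 and a dashed line at the deposited median. The deposited values centre on -0.20 and the rescaled values near 0.

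The genes with the largest falls named here had no overlap between the diets on the deposited scale, which includes the shift of all genes. The interferon-induced membrane protein gene Ifitm6 fell on the deposited scale from 8.31 ± 3.17 TPM (SD, n = 3) in AL to 3.81 ± 0.809 TPM (SD, n = 4) in CR, with a relative change of -0.73 ± 0.21. Clec4b1, a C-type lectin receptor of myeloid cells, fell on that scale from 8.85 ± 0.479 to 4.41 ± 1.37 TPM (relative change -0.72 ± 0.22), and the cytokine-like secreted protein gene Cytl1 from 47.1 ± 6.45 to 26.9 ± 9.1 TPM (-0.62 ± 0.23). Grrp1 went from 31.7 ± 3.44 to 17.8 ± 4.43 TPM (-0.62 ± 0.19) and Fam167b from 5.92 ± 1.59 to 2.91 ± 0.753 TPM (-0.64 ± 0.20), both called on that scale. Pcbd1, a cofactor of the transcription factor HNF1 and an enzyme of tetrahydrobiopterin recycling, fell on that scale from 24.1 ± 6.8 to 12.9 ± 3.59 TPM (-0.64 ± 0.24), and Nkapl from 9.12 ± 1.04 to 4.62 ± 1.08 TPM (-0.68 ± 0.17). The other transcripts of this group, AC168977.2, AC107711.4 and AC154760.1, had relative changes of -2.07, -1.27 and -0.81. After median-ratio scaling the adjusted p of these 10 genes lay between 0.0716 and 0.134, so that none of them was called there. For Pcbd1 and Cytl1 the diets overlapped after that scaling (two-sided exact permutation p = 0.114 for each).

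None of the 47 genes that rose and had a gene type in GENCODE M21 was protein coding. The 54 comprised 31 pseudogenes, 16 other noncoding genes and 7 genes absent from GENCODE M21, and the 45 with recovered reads had a median of 5.29 reads per library against 197 for all tested genes. The microRNA gene rows Mir6986 and Mir7116 had the largest changes among those named by the rule, at 1.04 ± 1.8 and 2.69 ± 2.42 TPM in AL (SD, n = 3) and 28.6 ± 16.4 and 26.4 ± 3.16 TPM in CR (SD, n = 4). These values rest on 1 and 2 reads in all of AL and 24 and 27 in all of CR. In GENCODE M21 they lie within the genes Rce1 and Acly, the latter encoding ATP citrate lyase, which supplies acetyl-CoA for fatty acid synthesis; neither has a row here. The pseudogene Mrps36-ps1 rose on the deposited scale from 45.6 ± 1.36 to 57.5 ± 5.86 TPM (0.54 ± 0.08), and the best match of its sequence, at 99.3% identity, was the mitochondrial ribosomal protein gene Mrps36, also without a row here. AC122861.3, CR555305.2 and CT025601.1 had relative changes of 2.41 ± 0.39, 0.89 ± 0.20 and 0.60 ± 0.12. The 5 genes that also passed after median-ratio scaling were Mir6946, named by the rule, and Gm22200, Gm13205, Gm17147 and Gssos2, named after their values were seen, with 2.64 to 6.33 TPM in CR. Gm22200, Mir6946 and Gssos2 were listed at 0 in all 3 AL libraries and rested on 4, 6 and 34 reads in CR, while Gm13205 and Gm17147 had 1 and 4 reads in AL and 37 and 41 in CR. All 5 were under 1 TPM in every AL library, so they met the filter of 4 libraries through CR alone. With any CR library left out they could not meet it. Without any single CR library limma called 0 genes after that scaling, with 2287 to 2464 at an unadjusted p under 0.05, against 12 without AL2, 3 without AL3 and 71 without AL4.

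Among the coactivators and adipose genes that the rule named before the data were examined, the coactivators with a row did not pass the test on either scale. Ncoa5 was at 22.8 ± 2.86 TPM in AL (SD, n = 3) and 21.9 ± 3.23 TPM in CR (SD, n = 4), with a relative change of 0.15 ± 0.11, and was -0.06 on the deposited scale. Ncoa6, at 17.4 ± 1.96 and 15.3 ± 1.03 TPM, had a relative change of 0.04 ± 0.09 and -0.17 on the deposited scale, and Ncoa7, at 6.24 ± 1.63 and 4.48 ± 0.422 TPM, one of -0.20 ± 0.14. Ncoa1, Ncoa2, Ncoa3, Ncoa4 and the fatty acid synthase gene Fasn were not analysed here, and neither was splicing, since the table gives 1 value per gene. The adipokine genes Lep (leptin) and Adipoq (adiponectin) had relative changes of -0.06 ± 0.30 and -0.14 ± 0.11, the first spanning 769 to 1885 TPM within AL. The adipocyte regulator Pparg stood at 349 ± 87.1 and 336 ± 20.6 TPM, a relative change of 0.19 ± 0.16 but -0.03 on the deposited scale, and the mitochondrial coactivator Ppargc1a at 8.09 ± 2.53 and 8.12 ± 1.39 TPM. Ucp1, the uncoupling protein of thermogenic fat, averaged 2.42 ± 3.28 TPM in AL and 6.31 ± 2.46 TPM in CR, a relative change of 1.56 ± 0.57. It stood at 6.20 TPM in AL2, 0.401 in AL3, 0.663 in AL4 and 2.79 to 8.51 in CR. None of these 8 genes passed the limma test on the deposited scale (adjusted p = 0.0688 for Adipoq and 0.114 for Ucp1) or after rescaling (adjusted p = 0.127 for Ucp1). The 95% confidence interval of the relative change was -0.11 to 0.41 for Ncoa5 and 0.24 to 2.88 for Ucp1.

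**Figure D3:**
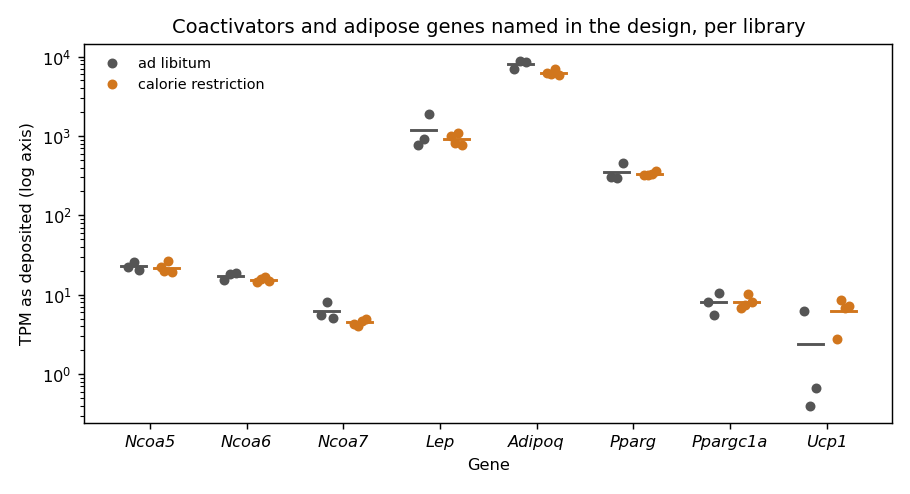
TPM per library is plotted on a log axis for the 8 coactivators and adipose genes named beforehand by the rule that have a row. Points stand for the 3 AL (grey) and 4 CR (orange) libraries and lines for the group means. Ucp1 ranges from 0.401 to 6.20 TPM in AL and from 2.79 to 8.51 TPM in CR, so that the diets overlap.

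The most abundant transcripts of the depot included those of the secreted protease Cfd (adipsin), the carbonic anhydrase Car3, Adipoq, Cyp2e1 and B2m, the light chain of class I histocompatibility molecules. Of these 5, B2m fell on the deposited scale, from 6544 ± 947 TPM in AL (SD, n = 3) to 4679 ± 245 TPM in CR (SD, n = 4), with a relative change of -0.26 ± 0.12. Cfd was at 56653 ± 5306 and 39203 ± 2447 TPM, with a relative change of -0.31 ± 0.16 and an adjusted p of 0.0675 on the deposited scale. Car3 and Cyp2e1 had relative changes of -0.06 ± 0.14 and 0.12 ± 0.11, the second being -0.09 on the deposited scale.

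Of 50 gene lists fixed before the data were examined, 395 of the 1122 members were tested, and 25 lists held a member called on the deposited scale while 0 did after median-ratio scaling. The 596 members without a row were not analysed here, so each count below covers part of its list and leaves out any member with a deposited FDR under 0.05. Adjusted over the list alone after that scaling, members of 17 lists passed, and those genes were named after their values were seen. That adjustment does not correct for the number of lists. After that scaling 29.0% of all tested genes had an unadjusted p under 0.05, so members that pass it do not by themselves set a list apart. De novo lipogenesis could not be assessed, since 0 of its 22 members had a row. In triglyceride synthesis 2 of 4 tested members rose relative to the typical gene when adjusted over the list alone, the acyltransferase Agpat3 (relative change 0.31 ± 0.07) and the lipid droplet formation gene Fitm2 (0.25 ± 0.06). That list was not called by camera on the deposited scale (adjusted p = 0.682) or after rescaling (adjusted p = 0.623), nor by fry after rescaling (adjusted p = 0.165). In lipolysis and the lipid droplet, 1 of 9 rose in that way, Mgll, the monoglyceride lipase that completes triglyceride breakdown (0.41 ± 0.11). The droplet coat genes Plin1 and Plin3 and the insulin-responsive phosphodiesterase Pde3b fell on the deposited scale, with relative changes of -0.14, -0.32 and -0.17. Of 4 tested genes of fatty acid oxidation, the peroxisomal thiolase gene Acaa1a (0.26 ± 0.06) was among those that rose adjusted over the list alone, and Ehhadh, the peroxisomal bifunctional enzyme, fell (-0.31 ± 0.12). Acsl5, an acyl-CoA synthetase, was the 1 of 5 fatty acid uptake genes that rose adjusted over the list alone (0.31 ± 0.08), and the fatty acid transporter Cd36 was at -0.01 ± 0.08.

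In branched-chain amino acid catabolism 7 of 9 tested members passed adjusted over the list alone after median-ratio scaling, and 2 of 9 were called over all genes on the deposited scale. Those that rose included the aminotransferase Bcat2 (0.30 ± 0.10), the isovaleryl-CoA dehydrogenase Ivd (0.37 ± 0.09), Acadsb (0.28 ± 0.05) and Pcca (0.38 ± 0.14). Those that fell were Dbt, a subunit of the branched-chain ketoacid dehydrogenase that commits the carbon skeletons to oxidation (-0.31 ± 0.05), and Mccc2, in leucine breakdown (-0.35 ± 0.11). The list as a whole was not called by camera after rescaling (adjusted p = 0.623).

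Genes of insulin and growth factor signalling also went both ways. Adjusted over the list alone 6 of 11 tested genes passed after rescaling, and 6 of 11 fell over all genes on the deposited scale. The list as a whole was not called by camera after rescaling (adjusted p = 0.789). The insulin receptor gene Insr (relative change 0.29 ± 0.09) and the kinase genes Akt1 (0.33 ± 0.08) and Akt2 (0.38 ± 0.06) rose adjusted over the list alone. The phosphoinositide 3-kinase subunit genes Pik3r1 and Pik3ca and the growth factor gene Igf1 fell, by both measures, with relative changes of -0.52 ± 0.19, -0.36 ± 0.10 and -0.33 ± 0.12. Igfbp4, which binds insulin-like growth factors, fell on the deposited scale, at 767 ± 55.2 TPM in AL (SD, n = 3) and 605 ± 32.6 TPM in CR (SD, n = 4), a relative change of -0.12 ± 0.06.

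Transcriptional regulators were represented by 17 tested nuclear receptor coregulators, 23 nuclear receptors and energy regulators and 8 adipogenic transcription factors. Ncor1, the corepressor that holds nuclear receptors silent, fell from 87.2 ± 11.4 TPM in AL (SD, n = 3) to 56.0 ± 4.57 TPM in CR (SD, n = 4). It was called over all genes on the deposited scale and, with a relative change of -0.41 ± 0.08, adjusted over the list alone after rescaling. The acetyltransferase gene Ep300 also fell on the deposited scale (relative change -0.29 ± 0.09), and no other coregulator was called there. Of the nuclear receptors and energy regulators 7 fell on the deposited scale and 0 passed adjusted over the list alone after rescaling. Those that fell included the AMP-activated kinase subunit gene Prkaa1 (-0.26 ± 0.06), the thyroid hormone receptor gene Thra (-0.12 ± 0.07) and the retinoic acid receptor gene Rarg (-0.33 ± 0.09). Among adipogenic factors the glucocorticoid receptor gene Nr3c1 (-0.31 ± 0.10) and Gata2 (-0.38 ± 0.13), which restrains adipocyte differentiation, fell by both measures, and Rxra fell on the deposited scale alone. Nr3c1 did not pass when adjusted over the nuclear receptors and energy regulators or the glucocorticoid-responsive genes (limma, adjusted p = 0.0776 and 0.0675 after rescaling). The liver X receptor gene Nr1h3 rose adjusted over the list alone (0.21 ± 0.07, though -0.01 on the deposited scale).

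Splicing factors, of interest because the study examined splicing, were well covered, with 65 of 86 tested. Over all genes 15 of the 65 fell on the deposited scale and 0 rose, where 17.6% of all tested genes fell. At an unadjusted p under 0.05 after rescaling stood 17 of the 65, where 29.0% of all tested genes did. The list was not called by camera after rescaling (adjusted p = 0.789), so it did not stand apart from the other genes. Adjusted over the list alone after rescaling 6 rose and 2 fell. Those that rose were Srsf1 (0.33 ± 0.08), Srsf10 (0.29 ± 0.06), Hnrnpc (0.31 ± 0.06), Qk (0.35 ± 0.08), Snrpb (0.34 ± 0.08) and the spliceosome core gene Prpf8 (0.30 ± 0.06). Those that fell were the RNA-binding protein gene Khdrbs1, also called Sam68 (-0.30 ± 0.07), and the nuclear speckle gene Son (-0.35 ± 0.07), both called on the deposited scale as well. Ptbp3 and Celf2 fell on that scale too, and their relative changes were -0.29 ± 0.09 and -0.19 ± 0.06.

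In the lists of genes that make, fold and degrade proteins, members called over all genes on the deposited scale all fell. Those that passed adjusted over the list alone after rescaling went both ways in each list. Of 54 tested cytosolic ribosomal protein genes 33 fell on the deposited scale, for example Rps4x from 352 ± 26.9 TPM in AL (SD, n = 3) to 233 ± 3.44 TPM in CR (SD, n = 4). The list was the 1 of 37 that camera called there, as lower (adjusted p = 1.87e-05). That call was lost with an estimated correlation (adjusted p = 0.940) and after rescaling (adjusted p = 0.458), and its median relative change was -0.06. Adjusted over the list alone after rescaling, Rps4x (-0.38 ± 0.05), Rpl5, Rps3 and Rps21 fell, and Rpl18 (0.26 ± 0.06) and Rps19 (0.29 ± 0.06) rose. In the unfolded protein response the disulfide isomerase genes Pdia3 (-0.26 ± 0.07) and Pdia6 (-0.27 ± 0.06) fell and the asparagine synthetase gene Asns rose (0.41 ± 0.11), adjusted over the list alone. In that list 6 of 18 members, with Calr and Herpud1, fell over all genes on the deposited scale. The proteasome genes Psmc2, Psmc5 and Psmd11 rose (0.28, 0.31 and 0.31) and the immunoproteasome gene Psmb10 fell (-0.32), 4 of 6 adjusted over the list alone against 1 of 6 over all genes on the deposited scale. Of 25 autophagy and lysosome genes, 3 rose adjusted over the list alone, namely Ctsb (0.37 ± 0.08), Mcoln1 (0.25 ± 0.07) and Gabarap (0.20 ± 0.06, but -0.02 on the deposited scale). In that list 5 fell, which were the lysosomal enzyme genes Ctsa, Lipa and Hexa, the cholesterol transporter gene Npc1 and Gabarapl1, with relative changes from -0.33 to -0.25, and 8 were called lower over all genes on the deposited scale.

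Antioxidant genes included 3 that rose adjusted over the list alone, the superoxide dismutase gene Sod1 (0.36 ± 0.08), the catalase gene Cat (0.32 ± 0.09) and the thioredoxin gene Txn1 (0.28 ± 0.07). The secreted superoxide dismutase gene Sod3 fell (-0.36 ± 0.10), the 1 of 12 called over all genes on the deposited scale. Metallothionein Mt1, a glucocorticoid-responsive gene, fell on the deposited scale from 411 ± 76.8 TPM in AL (SD, n = 3) to 258 ± 30.6 TPM in CR (SD, n = 4), a relative change of -0.44 ± 0.15. The immediate early genes Jun and Klf6 fell there too, with relative changes of -0.26 ± 0.12 and -0.28 ± 0.12. So did the mitochondrial isocitrate dehydrogenase gene Idh2 and the glycolytic regulator Pfkfb1, at -0.23 ± 0.11 and -0.15 ± 0.07. The senescence list had 1 gene that rose and 1 that fell adjusted over the list alone, the cell cycle restrainer Rb1 (0.21 ± 0.06) and the lysosomal galactosidase gene Glb1 (-0.26 ± 0.08), and the replication factor gene Pcna fell on the deposited scale.

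Of 13 tested endothelial markers 5 fell on the deposited scale and 0 passed adjusted over the list alone after rescaling. Those that fell included the junction genes Pecam1 (relative change -0.22 ± 0.09) and Esam (-0.37 ± 0.13), Tek, the angiopoietin receptor gene (-0.33 ± 0.12), and Egfl7 (-0.18 ± 0.09). The endothelial list was not called by camera on the deposited scale (adjusted p = 0.682, or 0.940 with an estimated correlation) or after rescaling (adjusted p = 0.623). The pericyte marker Rgs5 fell on that scale from 129 ± 8.16 TPM in AL (SD, n = 3) to 89.9 ± 13.2 TPM in CR (SD, n = 4), a relative change of -0.31 ± 0.13. The tissue alarmin Il33 fell both there and adjusted over the list alone after rescaling, at 9.47 ± 1.52 and 5.31 ± 1.03 TPM (relative change -0.54 ± 0.15). The chemokine gene Cxcl9 and the cytotoxic granule gene Gzma fell on the deposited scale (-0.34 ± 0.13 and -0.94 ± 0.32). Gzma rested on 42 reads in all of AL and 13 in all of CR. The 9 tested T and NK cell markers had a median relative change of 0.14, and Gzma was the 1 called on the deposited scale. The matrix genes Col8a1 and Spon2 fell on that scale as well, with 3 of 41 matrix genes tested. Macrophage markers had 2 tested genes and 0 calls, with Trem2 and Marco at -0.80 ± 0.55 and -0.50 ± 0.25. Plasma cell genes varied between mice, with Igkc at 155 ± 33.4 TPM in AL and 221 ± 152 TPM in CR, and so did the muscle gene Myh1, which reached 64.2 TPM in AL2 and 0.325 to 9.80 TPM in the other libraries. The keratin gene Krt10 of skin was the 1 of 2 epidermal markers that rose adjusted over the list alone, at 6.57 ± 0.683 and 8.07 ± 0.319 TPM (0.45 ± 0.11). The Schwann cell gene Pmp22 was at -0.02 ± 0.22 and was not called. After rescaling, camera called 0 of 37 lists (smallest adjusted p = 0.458, 2 lists at an unadjusted p under 0.05) and fry called 0, against 14 by fry on the deposited scale.

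**Figure D4:**
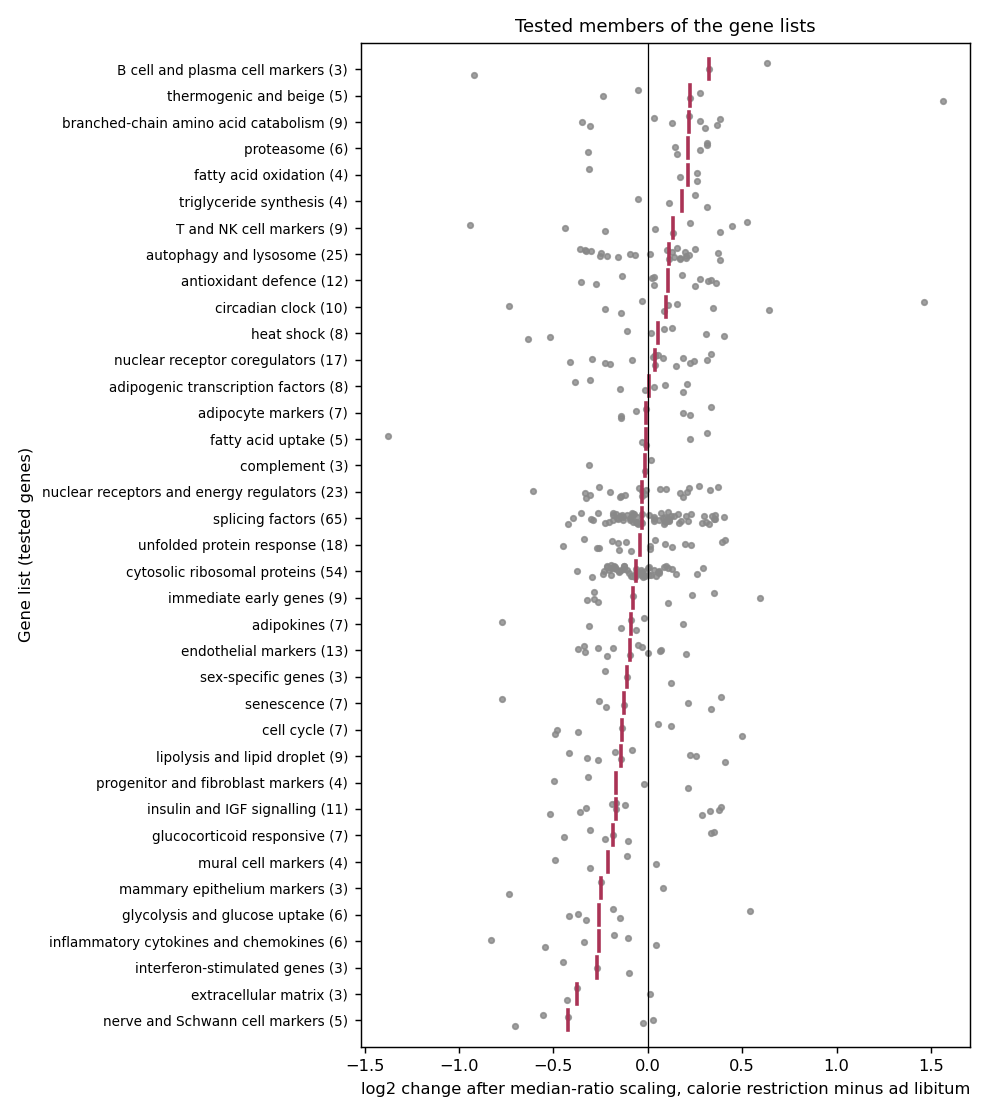
Each point is the relative log2 change of a tested member of 1 of the 37 lists with at least 3 tested genes, CR minus AL after median-ratio scaling, and each red bar is the median of its list. The ribosomal protein list has a median of -0.06 and branched-chain amino acid catabolism one of 0.22, with members on both sides of 0 in each.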

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

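The tests of the number of called genes and of the genes that differ after rescaling against other splits of the libraries, of the factor common to all rows, of counting noise and of overlapping genes were chosen only after the result was seen, and those of the 2-fold calls against other splits and of the pseudogene share were chosen before.

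On the deposited scale 1742 of the 1796 called genes (662 without CR2 to 1596 without AL4) were lower in CR. For the count and for the 60 calls of at least 2-fold (18 without CR2 to 84 without AL2), the highest of the other splits of the libraries gave 3 and 3. That argues against chance, but 35 splits allow no share under 0.0286, and genes of the same libraries are not independent. A candidate explanation is a single factor on every row, from the smaller share of the TPM total that these rows hold in CR. The median log2 change at a pseudocount of 0.1 was -0.22882, and the log2 ratio of the shares held was -0.23. Both are computed from the TPM of the same rows, so the typical gene shifted by about as much as the total. Their closeness cannot tell a common factor from a fall of many genes. Median-ratio scaling left 0 lower calls, as it moved the median log2 change of these 1742 genes from -0.48 (quartiles -0.56 and -0.38) to -0.27 (-0.36 and -0.17) at a median standard error of 0.101 before and 0.0953 after, and as the adjustment became stricter for the 355 of them that kept an unadjusted p no larger than that of the last call before (0.00908). Rows with a deposited FDR under 0.05 were not analysed, and that FDR followed the p after median-ratio scaling (Spearman's rho 0.768). The small number of calls after scaling may thus also follow from the choice of rows. An effect of the diet on many of the 1742 genes at once stays open as untested, because TPM are shares and cannot show a change in total RNA.

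None of the 47 higher calls with a gene type in M21 was protein coding (7 of the 54 had no type), most had few reads, and the 54 became 20, 12, 20 and 25 without CR1, CR2, CR3 and CR4 and 85, 32 and 90 without AL2, AL3 and AL4. The filter of 4 libraries can admit a row present only in CR but none present only in AL. With a CR library left out it admits neither. Counting noise alike in both diets is argued against, since after median-ratio scaling 55 pseudogene and noncoding rows with under 10 reads on average were higher in CR at an unadjusted p under 0.01, against at most 24 in any other of the 35 splits, although the other splits do not carry the smaller number of reads in CR. Pseudogene rows may instead take reads of a matching gene that has no row here, since for 63.33% of the higher-called pseudogenes with a match (19 of 30) the best match had no row, against 24.0% (264 of 1101) of the other pseudogenes (Fisher's exact p = 7.62e-06), and Gm11185, Gm6283 and Gm9211, for example, match Gapdh. Pseudogenes that match the same gene are not independent, so the Fisher's p of the pseudogenes may be too small. Noncoding rows within a protein-coding gene that has no row made up 43.75% of the higher calls of that type (7 of 16) and 25.5% of the rest (295 of 1158, Fisher's exact p = 0.144). Reads of the surrounding gene cannot be told apart from transcripts of these rows with so few calls, and a rise of the pseudogenes themselves under the diet was not tested.

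After median-ratio scaling 2865 genes had an unadjusted p under 0.05 and 5 were called. Chance is argued against for the 2865 by the 35 splits, of which the highest other gave 1256, although 35 splits allow no share under 0.0286. For the 5 calls chance is not taken as excluded, since the highest other split gave 4. Without any 1 of the CR libraries limma called 0 (2287 to 2464 at an unadjusted p under 0.05), but the 5 rows then fell below the filter of 4 libraries. Without AL2, AL3 and AL4 it called 12, 3 and 71. The rows with the smallest deposited FDR were not analysed here, and this scaling removes the shift of -0.22882, so a common factor may account for the excess of lower over higher calls but not for the excess at an unadjusted p that remains after it. A biological difference between the diets stays open for that excess, untested, as does a difference in cell composition.

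Within CR, 10 of 159 values tested had 1 library set apart from the other 3, where chance gives about 7.95. The gap to the nearest library divided by the whole range, compared with Dixon's 95% critical value, was 0.8602 for Acsl5 (lowest in CR1 at 50.5 TPM, others 59.9 to 61.4), 0.8607 for Cfd (highest in CR3 at 42836 TPM, others 37496 to 38240.0) and 0.8739 for Glb1 (lowest in CR4 at 27.3 TPM, others 28.6 to 28.8). It was 0.8746 for Idh2 (highest in CR3 at 215.5 TPM, others 186 to 190 TPM), 0.8388 for Ivd (lowest in CR1 at 288 TPM, others 311 to 316) and 0.8953 for Pcna (lowest in CR1 at 23.6 TPM, others close to 24.0). It was 0.8651 for Pfkfb1 (highest in CR2 at 40.3 TPM, others 36.8 to 37.3), 0.8653 for Prdm16 (highest in CR4 at 9.55 TPM, others 6.60 to 7.00) and 0.8401 for Qk (highest in CR4 at 92.5 TPM, others 78.4 to 80.7). For Trem2 it was 0.8601, with 5.38 TPM in CR2 and 0.261 to 0.978 TPM in the others. The 3 AL libraries are too few for this rule and were not tested.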

How the results depend on the processing

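The filters on 3 libraries and on recovered reads, voom, and leaving out libraries after median-ratio scaling were added after seeing the data. No paired analysis was possible because the column numbers (AL2 to AL4, CR1 to CR4) do not follow the mouse numbers of the labels and so carry no pairing. The replicate block was not run, nor was the count-based alternative (the table holds TPM) or any for Ncoa2 (no row). Of 157 genes taken by the naming rule or added later 77 were called; over 4611 values under alternatives 3297 were the same, 1085 lost the call, 32 gained it, 0 called genes reversed, and 197 uncalled values moved or changed sign. Of the 77, 72 lost the call under each rescaling, 41 stayed called under all alternatives without another scaling or test, and 35 lost it without 1 library (32 without AL3, 29 without CR2).

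The 1796 calls (54 higher, 1742 lower, 60 at least 2-fold, 1 list) became 5 (5 higher, 0 lower, 5 at least 2-fold) with median-ratio scaling, quantile normalization and totals without mitochondrial and the 20 top genes. Lists were 0, 1 and 0. Each removes most of the common shift. The p were compared for median-ratio scaling alone. There 355 of the lower calls kept an unadjusted p no larger than that of the last call before (0.00908) and lost the call by the adjustment over fewer small p. All 54 higher calls had a smaller unadjusted p there, yet 49 lost the call by the same adjustment. Without a filter the calls were 742 (21 higher, 721 lower, 37 at least 2-fold, 5 lists), partly since 25455 genes were tested. Voom and the exact permutation test per gene called 0 (0, 0; voom 0 at least 2-fold and 0 lists), with 2998 and 2525 at an unadjusted p under 0.05; the smallest permutation p, 0.0286, limits the latter. Higher calls were 22 at a mean TPM of at least 5, 87 with the first surrogate variable and 12 at a mean of at least 10 recovered reads; 2-fold calls were 8 at pseudocount 5, 11 at a mean TPM of at least 5 and 6 at a mean of at least 10 reads. Lists called were 0 with an estimated correlation and 14 by fry. Leaving out 1 library gave 662 (CR2) to 1596 (AL4) calls, 12 to 90 higher, 650 to 1506 lower and 18 (CR2) to 84 (AL2) at least 2-fold; without AL3, CR1, CR3 and CR4 the calls were 725, 765, 1032 and 1170 and the 2-fold calls 31, 31, 30 and 33. After median-ratio scaling it gave 0 (each CR) to 71 (AL4) calls, 12 without AL2 and 3 without AL3, and 2287 to 2774 genes at an unadjusted p under 0.05. The lowest library correlation, 0.9517, was 0.897, 0.938 and 0.9726 at pseudocounts 0.1, 0.5 and 5, 0.9594 with no filter, 0.9302 with the recomputed totals, 0.9707 at a mean of at least 10 reads, and 0.954 to 0.9615 without 1 library. Where no reason is given, the cause was not tested. Depth limits the rows with few reads, in which the simulation placed no change. In genes with many reads, 1.5-fold changes were recovered in 22.4% of simulated cases.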

Other observations

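The test of the gene lists against other splits and that of pseudogenes against their matching genes were both chosen before the result was seen, and the further subsets of the latter and the comparison with the authors' FDR were chosen after.

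Ribosomal protein genes made up the 1 list called on the deposited scale, and 30 of the 35 splits of the libraries called as many lists, the highest other 5, so chance cannot be excluded for a list call of this kind. Markers of nerve, of blood and of mesothelium and visceral fat gave 0 calls. The haemoglobin gene Hbb-bt was at 88.5 ± 7.76 TPM in AL (SD, n = 3) and 103 ± 23.8 TPM in CR (SD, n = 4), with a relative change of 0.41 ± 0.17, and the mesothelial gene Lrrn4 at 4.07 ± 1.1 and 4.54 ± 1.02 TPM. Krt19, the other tested member of the mesothelial list, was at 4.30 ± 0.266 and 2.31 ± 2.25 TPM, a relative change of -0.73 ± 0.43. The Y-linked genes Ddx3y and Uty had relative changes of 0.12 ± 0.07 (-0.09 on the deposited scale) and -0.11 ± 0.12. The neutrophil genes S100a8 and S100a9 stood at 3.28 ± 1.29 and 4.26 ± 1.97 TPM in CR, close to 3.74 ± 1.58 and 4.43 ± 1.68 TPM in AL. The chaperone gene Hsp90ab1 was at 1305 ± 257 and 1468 ± 148 TPM (0.40 ± 0.13), and the beige fat gene Otop1 at 15.9 ± 10.1 and 14.7 ± 2.31 TPM, neither of them called.

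Pseudogene rows may take reads of the gene they match. If so, their changes should follow those of the gene, with a rank correlation above 0.3. Across 821 pairs of a tested pseudogene and its tested best match, Spearman's rho of the relative changes was 0.4623 and Pearson's r 0.41 (permutation p = 1e-05, the smallest that 100000 resamples give). The rank correlation was 0.4928 over 585 pairs without ribosomal protein matches and 0.5135 over 471 pairs with 1 pseudogene per gene. Genes are not independent replicates, and a shared regulation of both members of a pair was not tested.

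Among genes in the rows analysed here, 484 with a deposited FDR under 0.1 in the authors' deposited table were higher and 478 lower after median-ratio scaling. The authors' FDR correlated across the 9883 tested genes with the p of the limma test at a Spearman's rho of 0.247 on the deposited scale and 0.768 after median-ratio scaling, and genes are not independent replicates.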
